A study of Bos taurus with 193 samples.

How the data were processed

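RNA sequencing counts were analysed from endometrial cytobrush samples of 193 lactating dairy cows, 1 library per cow, taken directly before artificial insemination. Per the labels, RNA was purified with a Qiagen RNeasy micro kit after bead homogenization, and libraries were made with the NEBNext Ultra II Directional kit on a mosquito LV pipetting robot. According to the submitters' processing notes, reads were trimmed with cutadapt 3.4, aligned with STAR 2.7.9, handled with SAMtools and counted with HTSeq. The genome build, the annotation and the HTSeq settings are not given in the sources used here. The deposited values are read counts, 1 table of 83120 annotated transcripts for all libraries, and were used as such.

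Because the counts are per transcript, reads that fitted more than 1 transcript had been set aside as ambiguous by the authors' counting. These were 49.5% of reads on average, against 37.3% assigned to a transcript, 10.7% that overlapped no transcript and 2.39% that were not unique in the genome. Counts were summed per gene with the RefSeq table of assembly ARS-UCD2.0, which pairs transcript names and locus tags with gene symbols, giving 55792 features. Names found by transcript carried 80.9% of the counts and names found by locus tag 11.4%. A further 6.67% stayed under a transcript name that the table did not hold. Each such name counted as a gene with 1 transcript, although it may belong to a named gene. Genes with several transcripts are measured only through reads specific to a single transcript, so their level is underestimated and may have no counts at all. Of 623 genes in the lists, 336 were tested, and of the 287 others 94 had 0 counts in all libraries and 28 were not in the count table.

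Between 10390177 and 21416004 reads per library were assigned, with a median of 15772174. The precision this gives was checked on simulated counts, drawn for each gene from a negative binomial distribution with its real mean and dispersion. The real library sizes and outcome groups were kept, and 200 genes were changed between the groups. Of 50 genes changed at each fold, 25 were recovered at 1.25-fold, 44 at 1.5-fold, 45 at 2-fold and 46 at 3-fold. There were 10 false calls among 170 calls. Each gene was drawn independently of the others. In the real counts genes vary together and single cows reach very high levels, so these 10 false calls do not describe them. The lowest mean correlation of a library with the others was 0.869, and the highest correlation of any pair was 0.973, so no library was a copy of another.

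Pregnant (n = 81) and nonpregnant (n = 112) cows were compared with the edgeR 4.0.16 quasi-likelihood F test, TMM normalization and filterByExpr (minimum count 10, minimum total 15), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Effects are log2 fold changes of pregnant over nonpregnant with their SE. Gene lists with at least 5 tested members (34 of 39) were tested by camera in limma 3.58.1 with the preset correlation of 0.01. List scores were the mean over members of log2 CPM (prior count 2) standardized per gene, compared by 100000 permutations of the labels, as were the scores of 10 principal components of the 2000 most variable genes and the rank of the cow number. Relations between 11 cell type lists were measured by Pearson's r and Spearman's rho with permutation p, pooled and within outcome groups. Outcome was predicted by an elastic net (glmnet 4.1.10, alpha 0.5) on the 2000 most variable genes of each training fold, in 5-fold cross-validation repeated 10 times, with 100 permutations of the labels and 2000 bootstrap resamples. Calls under other settings are given as a percent of the 11168 genes tested. Differences in spread were tested per gene by the Brown-Forsythe test on log2 CPM. Groupings, tests, gene lists, the rule for named genes and the settings to be varied were fixed before the data were examined.

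Genes named in the text were chosen by a rule. It takes the 15 higher and 15 lower genes of smallest p with a symbol, a mean of at least 1 CPM and an adjusted p under 0.05, up to 4 members of smallest p in each list described, 16 genes of interest in the reproductive tract, the 10 genes most often selected by the elastic net and the 10 of smallest p for spread. Names made of a locus number or a transcript name were treated as lacking a symbol for the 15 per direction. Of the genes of interest, PGR, OXTR, PTGS2, IL1B, CXCL8, ISG15 and FOXA2 could be tested.

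The sample titles hold a number per cow whose meaning the labels do not give. It was used only as a possible nuisance variable, in blocks below 20000, from 20000 to 45000 and above 45000, and as a rank. No paired analysis was possible because the labels give no number shared between pregnant and nonpregnant cows, and no herd, age or sequencing batch is given in the sources used here.

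Other settings fixed in advance for genes were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, the Wilcoxon test, robust edgeR, no filter and a mean of at least 5 CPM, leaving out libraries of low total or low correlation, and covariates for library composition, cow number, 5 cell list scores (1 of them, erythroid, with 1 tested member), 5 surrogate variables (sva 3.50.0) and 3 principal components. For lists under camera these were an estimated correlation, fry, DESeq2 size factors and covariates for cow number block and 5 cell list scores, and for list scores the median over members, unstandardized values and permutation within cow number blocks. For prediction they were a random forest (ranger 0.17.0, 500 trees), a linear support vector machine (e1071 1.7.16, cost 0.001), the 500 genes of smallest training-fold p, list scores, the cow number alone and 10 folds. For spread they were the Levene test from the mean and residuals after 5 cell list scores, and for principal components the 5000 most variable genes. Added after the data were seen were counts per transcript, a cap of each gene at its 95th percentile, the ambiguous share and the squamous list score as covariates, cows above 45000 only, genes with 1 transcript, members of at least 0.1 CPM, and leaving out each of 23 cows that had the highest level of a named gene. Also added were DESeq2 size factors and the cow number rank as a covariate for the list scores, prediction from IL1B alone and from the unfolded protein response score alone, comparison of predictions within 8 strata of cow number, and a test of each gene against the cow number rank. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Raw reads were not analysed here. The result of 1 of the called lists and its members is not reported here, and the list is left out of the figure.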

Results

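Endometrial RNA was sequenced from 193 lactating dairy cows, each sampled once by cytobrush from the uterine body directly before artificial insemination. A cytobrush is a small brush turned against the lining of the uterus, so it collects surface epithelial cells together with immune cells and some underlying tissue. The cows were grouped by the outcome of that insemination, with 81 recorded as pregnant and all others as nonpregnant, and each cow gave 1 library. Unless a smaller set is named, values of a group come from all its cows. Between 10390177 and 21416004 reads per library were assigned to an annotated transcript, with a median of 15772174. The groups did not differ detectably in this total, which averaged 15866488 ± 1279865 (SD, n = 81) in pregnant and 15641945 ± 1205062 (SD) in nonpregnant cows (2-sided permutation test, p = 0.218, adjusted p = 0.349 over 8 library measures). After counts were summed per gene, 11168 genes passed the expression filter and were tested. Genes with several annotated transcripts kept only reads specific to a single transcript. Of the 55792 features in the table, some of them single transcripts not matched to a gene, 22744 had 0 counts in all libraries. LTF and MUC1 were among these with 1 transcript under their name, so several transcripts per name do not account for every such feature. Absence of a gene below says nothing about its expression.

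The question behind the series was whether the transcriptome of the endometrium before insemination differs between cows that conceive and cows that do not, and whether it can predict the outcome. Several of the 15 genes of smallest p that were lower in cows that became pregnant act in inflammation or leukocytes, a grouping made after the genes were seen and not tested. IL1B, a proinflammatory cytokine, averaged 2.77 ± 3.12 CPM (counts scaled to library size; SD, n = 81) in pregnant and 24.1 ± 136 CPM (SD) in nonpregnant cows, a log2 fold change of -3.12 ± 0.39 (SE). CXCL8, a chemokine that attracts neutrophils, differed by -2.79 ± 0.41, and IL1A by -2.15 ± 0.34. IGFBP1, a binding protein of insulin-like growth factors, differed by -3.43 ± 0.49 and LAP, a beta-defensin, by -3.38 ± 0.56. The interferon-induced genes ISG15 and RSAD2 differed by -1.81 ± 0.26 and -1.49 ± 0.24, and MMP9, a matrix-degrading gelatinase stored in neutrophils, by -3.41 ± 0.54. Also lower were SRGN, the proteoglycan of immune cell granules (-1.34 ± 0.20), PLEK, a protein kinase C substrate of leukocytes and platelets (-1.69 ± 0.27), SLC11A1, a metal transporter of phagocytes (-2.32 ± 0.35), and ITGAM, the CD11b integrin chain (-2.02 ± 0.32). The glucose transporter SLC2A3 (-1.80 ± 0.24), the retinol-esterifying enzyme LRAT (-1.28 ± 0.20) and HCAR2, a receptor for niacin and ketone bodies (-1.60 ± 0.25), completed the 15 lower genes of smallest p.

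All 15 passed the edgeR quasi-likelihood test (2-sided, Benjamini-Hochberg adjusted over 11168 genes), with adjusted p from 1.7e-09 for IL1B to 6.4e-06 for LAP. The medians of the groups lay far closer than the means. For IL1B they were 1.82 CPM in pregnant and 2.38 CPM in nonpregnant cows, and the pregnant cow had the higher level in 42.3% of all pregnant-nonpregnant pairs. Of the 15 genes, SLC2A3 alone also passed a Wilcoxon rank-sum test (adjusted p = 0.0228), while IL1B did not (adjusted p = 0.38), nor did IGFBP1 (adjusted p = 0.908), which was higher in the pregnant cow in 51.8% of pairs. The medians of MMP9 were 0.359 CPM in pregnant and 0.328 CPM in nonpregnant cows, the other way from its means, with the pregnant cow higher in 50.4% of pairs (Wilcoxon adjusted p = 0.98). MMP9 was at 0.031 with limma-voom and at 0.46 with 5 cell list scores as covariates, of which 1 contains it, and did not pass in either. The medians of LAP, at 0.263 and 0.188 CPM, were also the other way (48.6% of pairs, Wilcoxon adjusted p = 0.928). A minority of nonpregnant cows had very high levels. For IL1B, 8 nonpregnant cows exceeded the highest pregnant cow (21.1 CPM), and the highest of them, nonpregnant replicate 66, reached 1341 CPM. Without nonpregnant replicate 66 the IL1B difference was -2.14. Single cows weighed more heavily on 4 of the genes. ISG15 moved to -1.18 without nonpregnant replicate 42, and without nonpregnant replicate 15 SLC11A1 moved to -0.78 (adjusted p = 0.0377), MMP9 to -2.02 (adjusted p = 0.0024), and ITGAM to -0.66 with its call lost (adjusted p = 0.0586). Among the 161 cows with a number above 45000, SLC11A1 (-0.66, adjusted p = 0.178) and ITGAM (-0.62, adjusted p = 0.169) did not pass, whereas IL1B (-3.31 ± 0.43) and CXCL8 (-2.98 ± 0.44) did.

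**Figure D1:**
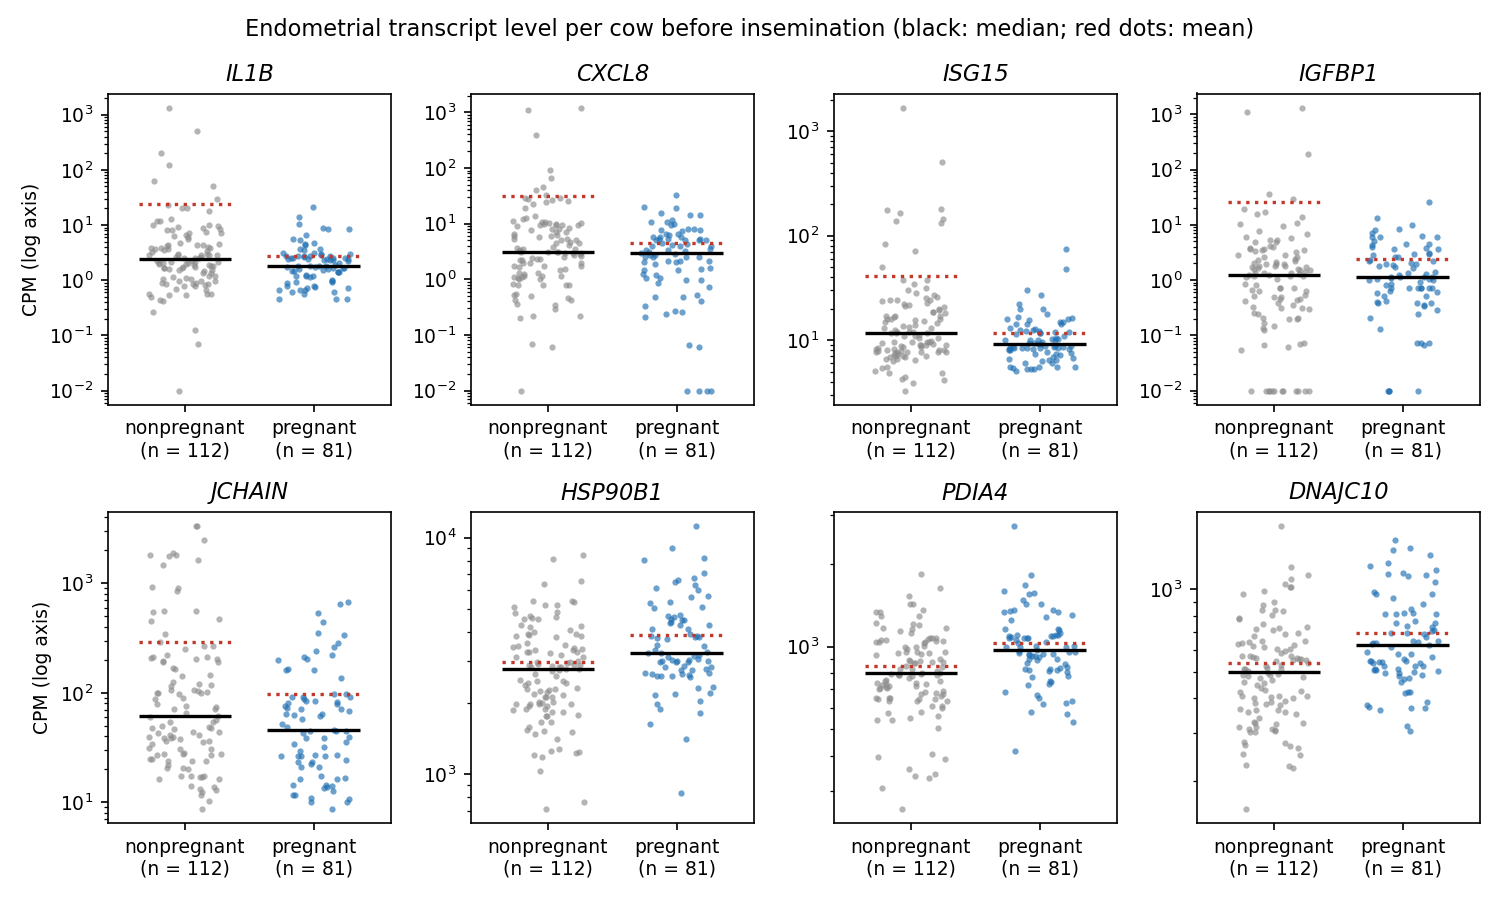
Level of 8 genes in each cow before insemination, in CPM on a log axis, for all nonpregnant (grey) and 81 pregnant (blue) cows; levels under 0.01 CPM are drawn at 0.01, black lines are medians and red dotted lines are means. For IL1B, CXCL8, ISG15 and IGFBP1 the means lie apart and the medians close together, because a few nonpregnant cows lie far above the rest, whereas for HSP90B1, PDIA4 and DNAJC10 the median is also higher in pregnant cows.

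The 15 higher genes of smallest p differed by small amounts, and many of them act in the endoplasmic reticulum, a grouping made after the genes were seen and not tested. HSP90B1, the chaperone GRP94, averaged 3874 ± 1809 CPM (SD, n = 81) in pregnant and 2972 ± 1417 CPM (SD) in nonpregnant cows, a log2 fold change of 0.38 ± 0.094 (SE). DNAJC10, a disulfide reductase that assists protein folding, averaged 694 ± 278 against 540 ± 245 CPM, a change of 0.36 ± 0.085. The protein disulfide isomerases PDIA3, PDIA4 and PDIA6 were higher by 0.32 ± 0.082, 0.28 ± 0.069 and 0.29 ± 0.073. Also higher were DDOST, a subunit of the oligosaccharyltransferase (0.28 ± 0.071), LMAN1, a cargo receptor between the endoplasmic reticulum and the Golgi apparatus (0.28 ± 0.073), SAR1B, a GTPase of COPII vesicles (0.20 ± 0.048), and MANEA, a mannosidase of the Golgi apparatus (0.22 ± 0.056). PLOD3, which hydroxylates lysines of collagen (0.24 ± 0.057), TAPBP, the tapasin of peptide loading on MHC class I (0.23 ± 0.057), and PON2, a paraoxonase (0.27 ± 0.071), were also higher. The remaining members of the 15 were SPTY2D1 (0.20 ± 0.049), ZNF792 (0.14 ± 0.035) and RAB7A, a GTPase of late endosomes (0.35 ± 0.089), whose 3 annotated transcripts left it only 3.67 CPM of assignable reads. The edgeR adjusted p ran from 0.0029 for DNAJC10 to 0.0083 for MANEA, and all but MANEA (adjusted p = 0.0722) also passed the Wilcoxon test. The HSP90B1 level was higher in the pregnant cow in 66.4% of pairs. With the share of ambiguous reads as a covariate HSP90B1 was at 0.32 ± 0.095 (adjusted p = 0.0666) and DNAJC10 at 0.29 ± 0.083 (adjusted p = 0.0644). With limma-voom they were at 0.34 ± 0.086 (adjusted p = 0.053) and 0.29 ± 0.077 (adjusted p = 0.0593). Neither gene passed in either setting. With 5 cell list scores as covariates HSP90B1 was at 0.25 ± 0.081 and did not pass (adjusted p = 0.0877), while DNAJC10 did (0.27 ± 0.077, adjusted p = 0.0496). With 3 principal components as covariates they were at 0.27 ± 0.079 (adjusted p = 0.0756) and 0.31 ± 0.073 (adjusted p = 0.0178). With the cow number block as a covariate all 15 passed. RAB7A itself rose with the cow number, by 0.49 ± 0.075 per 100 ranks with the outcome in the model (edgeR adjusted p = 6.3e-08). Among the 161 cows with a number above 45000 PDIA3 (0.29, adjusted p = 0.0509), DDOST (0.25, adjusted p = 0.0534), PON2 (0.23, adjusted p = 0.0762) and MANEA (0.19, adjusted p = 0.0797) did not pass. HSP90B1 did (0.36 ± 0.099, adjusted p = 0.0286).

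Across all genes, 657 of 11168 were called at an adjusted p under 0.05, 146 higher and 511 lower in pregnant cows (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 131 differed at least 2-fold, every one of them lower in pregnant cows. When outcomes were shuffled among the same cows, a median of 15 genes was called, with 191 as the highest. Shuffled outcomes gave up to 79 called genes of at least 2-fold in either direction, and at most 1 gene by the Wilcoxon test. The median log2 fold change of all tested genes was -0.0245. A nonpregnant cow had the highest level for 504 of the 511 lower genes, against 8272 of all 11168 genes, and a median of 7 nonpregnant cows lay above every pregnant cow. Calling genes as lower in part selects for this, and it was not counted with shuffled outcomes. The highest cow was nonpregnant replicate 15 for 124 of the 511, and without it 502 genes were called. The Wilcoxon test called 73 higher and 38 lower genes, and shared 61 higher and 38 lower genes with the edgeR test. By limma-voom 6 genes were called, 3 higher and 3 lower. With 5 cell list scores as covariates 115 were called, 13 of them higher. With 5 surrogate variables 91 higher and 46 lower genes were called, and with the share of ambiguous reads 3 higher and 84 lower. With the cow number block as a covariate 494 genes were called (134 higher, 360 lower), and within the 161 cows above 45000, 221 (36 higher, 185 lower).

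All 5 measured B and plasma cell markers fell, with the same 5 called when adjusted over the list alone. The Wilcoxon test called 0 of them, with 4 at an unadjusted p under 0.05. JCHAIN, the joining chain of secreted antibodies, averaged 98.1 ± 134 CPM (SD, n = 81) in pregnant and 288 ± 614 CPM (SD) in nonpregnant cows (log2 fold change -1.56 ± 0.31), and MS4A1, which encodes CD20, differed by -1.46 ± 0.28, POU2AF1, a B cell coactivator, by -1.23 ± 0.22 and MZB1, a plasma cell chaperone, by -0.85 ± 0.18. As a list these were lower by limma camera (2-sided, adjusted p = 0.000125 over 34 lists; adjusted p = 0.176 with an estimated correlation). Of 5 monocyte, macrophage and dendritic cell markers 4 fell, and 4 when adjusted over the list alone, among them C1QB, a complement chain made by macrophages (-1.25 ± 0.23), FCGR1A, a high-affinity antibody receptor (-0.92 ± 0.22), CSF1R, the receptor for macrophage growth factor (-0.60 ± 0.15), and MSR1, a scavenger receptor (-0.77 ± 0.23). The list passed camera (adjusted p = 0.00858; adjusted p = 0.347 with an estimated correlation) and not the rotation test fry (adjusted p = 0.0671). The Wilcoxon test called 0 of these 5 markers (4 at an unadjusted p under 0.05) and 0 of the T and NK cell markers (3 unadjusted). Without nonpregnant replicate 15, C1QB was at -0.67 (adjusted p = 0.011), and FCGR1A (-0.36, adjusted p = 0.208), CSF1R (-0.37, adjusted p = 0.0566) and MSR1 (-0.48, adjusted p = 0.189) were no longer called. With the cow number block as a covariate FCGR1A (-0.51, adjusted p = 0.116) and MSR1 (-0.60, adjusted p = 0.124) were not called either, and among cows above 45000 nor was CSF1R (-0.34, adjusted p = 0.161). Of 12 T and NK cell markers 1 fell, the costimulatory receptor CD27 (-0.66 ± 0.17), and 3 when adjusted over the list alone, while CD8B was at -0.36 ± 0.12 (adjusted p = 0.0664), and the list passed camera (adjusted p = 0.00858; adjusted p = 0.44 with an estimated correlation) and not fry (adjusted p = 0.165). The 5 neutrophil markers that could be measured did not pass as a list (camera adjusted p = 0.838), 1 of them fell, MMP9, and 2 when adjusted over the list alone, and MMP25 was at -0.43 ± 0.16 (adjusted p = 0.0852). Across cows the score of these 5 rose with mucus-secreting (r = 0.43) and ciliated cell markers (r = 0.39), and with B and plasma cell markers (r = 0.48). Its r was 0.12 with T and NK cell markers and -0.19 with general epithelial markers. How well this score measures neutrophils was not tested. With members of at least 0.1 CPM in place of the expression filter, 8 neutrophil markers were measured and passed camera as lower (adjusted p = 0.0363). Their score did not pass (permutation adjusted p = 0.093). By edgeR without a filter, members called as lower included TREM1 (-3.92 ± 0.49), OSM (-2.75 ± 0.38), CXCR1 (-2.67 ± 0.42) and CXCR2 (-1.85 ± 0.43). Their adjusted p ran from 2.4e-10 for TREM1 to 0.002 for CXCR2, all at low levels. The more abundant VNN2 (0.0096 ± 0.18) and PGLYRP1 (0.20 ± 0.15) pointed up and were not called. These members were chosen after their values were seen.

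Of 7 stromal fibroblast markers 5 fell, and 7 when adjusted over the list alone. SFRP4, a secreted Wnt inhibitor, differed by -2.14 ± 0.41, the collagen chains COL3A1 and COL1A2 by -0.92 ± 0.25 each, and the fibroblast surface protein THY1 by -0.86 ± 0.24. The list was lower by camera (adjusted p = 0.00349; adjusted p = 0.364 with an estimated correlation) and did not pass fry (adjusted p = 0.083). By the Wilcoxon test 0 stromal markers were called (2 at an unadjusted p under 0.05) and 0 smooth muscle markers (3 unadjusted). All 5 smooth muscle markers fell, and all 5 when adjusted over the list alone, with LMOD1 at -1.19 ± 0.26, SYNPO2 at -1.31 ± 0.36, the intermediate filament desmin (DES) at -1.44 ± 0.40 and enteric smooth muscle actin (ACTG2) at -1.81 ± 0.52. The list passed camera (adjusted p = 0.00668; adjusted p = 0.377 with an estimated correlation) and not fry (adjusted p = 0.088), but for 3 of these genes the call rested on nonpregnant replicate 19. Without that library DES was at -0.52 (adjusted p = 0.431), SYNPO2 at -0.80 (adjusted p = 0.141) and ACTG2 at -0.75 (adjusted p = 0.392). With the cow number block as a covariate COL3A1 (-0.78, adjusted p = 0.0518), COL1A2 (-0.76, adjusted p = 0.0624), DES (-0.74, adjusted p = 0.288), SYNPO2 (-0.83, adjusted p = 0.18) and ACTG2 (-1.07, adjusted p = 0.238) did not pass, and among cows above 45000 nor did THY1 (-0.72, adjusted p = 0.106) and LMOD1 (-0.74, adjusted p = 0.0954), while SFRP4 did (-2.08 ± 0.44, adjusted p = 0.00146).

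Few epithelial markers were called. Of 11 general epithelial markers 1 rose, the polarity gene CRB3 (0.13 ± 0.039, adjusted p = 0.0291), and 1 when adjusted over the list alone, and the adhesion molecule EPCAM was at 0.086 ± 0.040 (adjusted p = 0.208). Among cows above 45000 CRB3 was at 0.11 and did not pass (adjusted p = 0.119). The list did not pass camera (adjusted p = 0.295), and its median log2 fold change was -0.0076 although the test pointed up. None of 7 glandular markers passed edgeR over all genes, with 1 at an unadjusted p under 0.05, 0 by the Wilcoxon test and 1 lower when adjusted over the list alone. The gland transcription factors SOX17 and FOXA2 were at -0.17 ± 0.058 (adjusted p = 0.0521) and -0.16 ± 0.13 (adjusted p = 0.516). None of 8 ciliated cell markers passed by either test or when adjusted over the list alone, with 0 at an unadjusted p under 0.05, and the axonemal dynein DNAH9 was at -0.25 ± 0.15 (adjusted p = 0.362). Of 6 mucus-secreting cell markers 1 fell, the mucin MUC5AC (-1.35 ± 0.25, adjusted p = 5.9e-05), and 1 when adjusted over the list alone, whereas AGR2 (0.33 ± 0.14, adjusted p = 0.158), TFF3 (0.24 ± 0.14, adjusted p = 0.325) and TFF1 (0.41 ± 0.25, adjusted p = 0.379) did not pass. The medians of MUC5AC went the other way, 85.9 CPM in pregnant and 77.3 CPM in nonpregnant cows, with the pregnant cow higher in 55.5% of pairs (Wilcoxon adjusted p = 0.586). Capped at its 95th percentile MUC5AC was at 0.034 and not called. The mucus list was higher by camera (adjusted p = 0.00858; adjusted p = 0.347 with an estimated correlation), with a median of 0.18 and a mean of -0.069 that differ in sign. Of 6 squamous markers 1 fell, KRT5 (-1.29 ± 0.36, adjusted p = 0.0144), and 2 when adjusted over the list alone, although its median was 24.3 CPM in pregnant and 14.3 CPM in nonpregnant cows. Without the nonpregnant cow of highest KRT5 level (4540 CPM) KRT5 was at -0.66 and no longer called (adjusted p = 0.233), and with the cow number block as a covariate at -1.05 (adjusted p = 0.0641). The squamous list did not pass camera (adjusted p = 0.0503), which pointed up against a median of -0.41. It passed as higher with the cow number block as a covariate (adjusted p = 0.0395), with DESeq2 size factors (adjusted p = 0.042) and with 9 members of at least 0.1 CPM (adjusted p = 0.0363). It did not with 5 cell list scores as covariates (adjusted p = 0.26) or an estimated correlation (adjusted p = 0.415).

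Of 13 inflammatory cytokines and chemokines 7 fell, and 10 when adjusted over the list alone, led by IL1B, CXCL8, IL1A and PTX3, a long pentraxin of innate defence (-1.65 ± 0.34). The list was lower by camera (adjusted p = 0.000901; adjusted p = 0.347 with an estimated correlation) and did not pass fry (adjusted p = 0.064) or as a score. The Wilcoxon test called 0 of the 13, with 1 at an unadjusted p under 0.05. PTX3 was at -0.92 (adjusted p = 0.0375) without nonpregnant replicate 22 and at -0.91 (adjusted p = 0.109) among cows above 45000. Of 15 interferon-stimulated genes 9 fell, and 13 when adjusted over the list alone, all 15 having negative fold changes. Besides ISG15 (-1.18 without nonpregnant replicate 42) and RSAD2, these included the oligoadenylate synthetase OAS2 (-1.68 ± 0.28) and IFIT2, which binds viral RNA (-0.97 ± 0.16). This list had a camera adjusted p of 1.7e-05 (adjusted p = 0.347 with an estimated correlation) and did not pass fry (adjusted p = 0.0704) or as a score. The Wilcoxon test called 1 of the 15, with 8 at an unadjusted p under 0.05. Of 8 cell cycle genes 1 fell, cyclin A2 (CCNA2, -0.56 ± 0.18), and 3 when adjusted over the list alone, while cyclin B2 (CCNB2) was at -0.61 ± 0.24 (adjusted p = 0.104). The cell cycle list passed camera (adjusted p = 0.0313; adjusted p = 0.44 with an estimated correlation), but without nonpregnant replicate 12 neither it (adjusted p = 0.0522) nor CCNA2 (-0.47, adjusted p = 0.0822) passed, and with the cow number block CCNA2 was at -0.54 (adjusted p = 0.0641).

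Of 9 measured genes of the unfolded protein response 5 rose, and 7 when adjusted over the list alone, with HSP90B1, PDIA4 and PDIA6 given above and DNAJC3, an inhibitor of the kinases that slow translation, at 0.22 ± 0.069 (adjusted p = 0.0332). All 9 fold changes were positive, with a median of 0.25, and the list was higher by camera (adjusted p = 1.9e-07; adjusted p = 0.176 with an estimated correlation). DNAJC3 was no longer called without pregnant replicate 39 (0.18, adjusted p = 0.0898) or among cows above 45000 (0.19, adjusted p = 0.178). With the share of ambiguous reads as a covariate HSP90B1, PDIA4 (0.21, adjusted p = 0.107), PDIA6 (0.26, adjusted p = 0.06) and DNAJC3 (0.12, adjusted p = 0.414) did not pass. None of these 4 passed with limma-voom, nor with 5 cell list scores as covariates, where PDIA4 was at 0.17 (adjusted p = 0.0852), PDIA6 at 0.20 (adjusted p = 0.0767) and DNAJC3 at 0.12 (adjusted p = 0.26). With 3 principal components as covariates none of the 4 passed either (adjusted p from 0.0756 to 0.0956). The Wilcoxon test called 3 of the 9, with 6 at an unadjusted p under 0.05. Of 8 estrogen-responsive genes 6 had positive fold changes, and the list was higher by camera (adjusted p = 0.00693; adjusted p = 0.109 with an estimated correlation), with a median of 0.16 and a mean of -0.042 that differ in sign. The only member called over all genes was PDZK1, a scaffold protein of the apical membrane, which fell (-0.68 ± 0.20, adjusted p = 0.0186). PDZK1 was at -0.39 (adjusted p = 0.17) without nonpregnant replicate 39, and at -0.56 (adjusted p = 0.0782) with the cow number block. When adjusted over the list alone 1 member rose and 2 fell, and over all genes the retinoic acid receptor RARA (0.16 ± 0.066, adjusted p = 0.118), the coregulator NRIP1 (0.075 ± 0.034, adjusted p = 0.191) and the chemokine CXCL12 (-0.76 ± 0.26, adjusted p = 0.062) did not pass.

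In total 12 of the 34 lists with at least 5 measured members were called by camera, and 13 with the cow number block as a covariate. With correlations estimated from the data 0 lists passed camera, 3 having an unadjusted p under 0.05, and the rotation test fry called 3, namely B and plasma cell markers (adjusted p = 0.00741), estrogen-responsive genes (adjusted p = 0.00116) and the unfolded protein response (adjusted p = 0.00741).

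The same 3 lists stood out when each cow was given a score per list, the mean over members of standardized log2 CPM. The estrogen-responsive score was higher in pregnant cows by 0.239 ± 0.054 (SE), and a pregnant cow had the higher score in 65.8% of pairs (2-sided permutation test, p = 4e-05, adjusted p = 0.00136 over 34 lists). The unfolded protein response score was higher by 0.407 ± 0.118 (permutation p = 0.00074, adjusted p = 0.00839), with 62.6% of pairs in that direction. The B and plasma cell score was lower, by -0.396 ± 0.104 (permutation p = 0.00057, adjusted p = 0.00839), the pregnant cow being higher in 38.3% of pairs. Scores of macrophage markers (-0.276 ± 0.106), mucus-secreting cell markers (0.257 ± 0.0927), inflammatory genes (-0.224 ± 0.0789) and interferon-stimulated genes (-0.266 ± 0.0962) did not pass, each with a permutation adjusted p of 0.0566. The general epithelial score differed by 0.094 ± 0.0725 (adjusted p = 0.375). With labels permuted within the 3 cow number blocks the adjusted p was 0.00102 for the estrogen-responsive, 0.00442 for the unfolded protein response and 0.00884 for the B and plasma cell score. Among the cows above 45000 (73 pregnant, 88 nonpregnant) the differences were 0.249, 0.371 and -0.383 (permutation adjusted p = 0.00068, 0.0301 and 0.0301). The other blocks held 3 and 5 pregnant cows, too few for a value of their own.

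**Figure D2:**
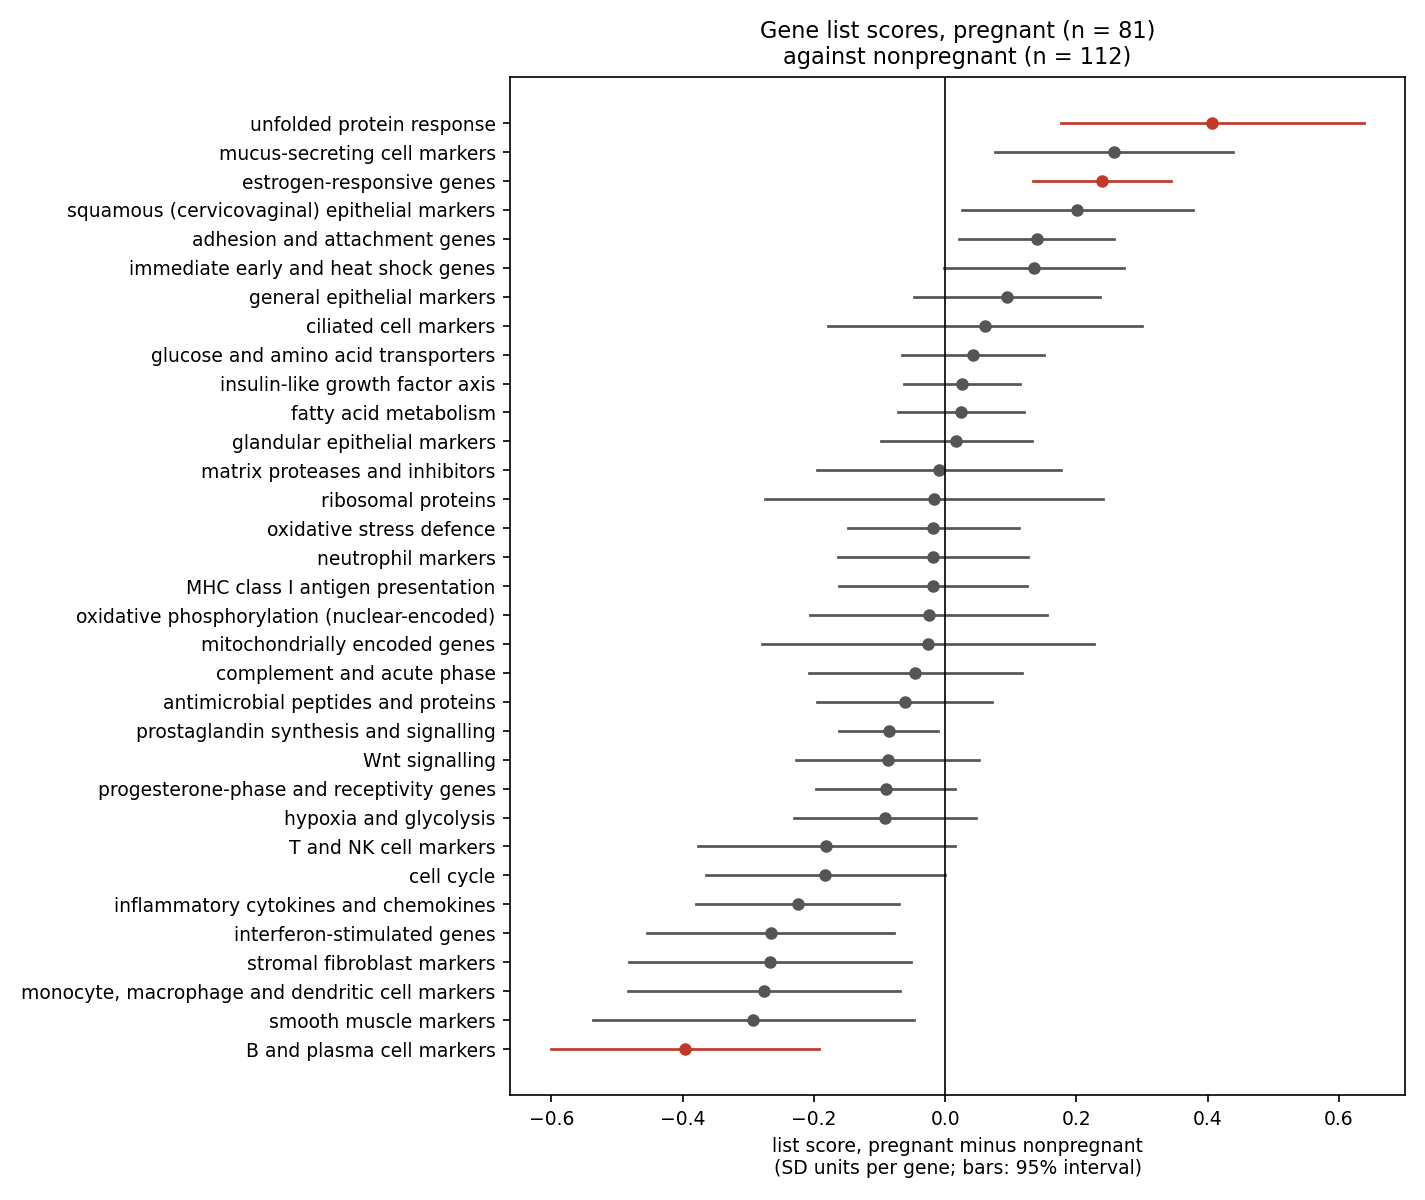
Difference in mean list score between 81 pregnant and all nonpregnant cows for the tested gene lists, in standard deviations per gene, with 95% intervals; red marks a permutation adjusted p under 0.05. The unfolded protein response (0.407) and estrogen-responsive genes (0.239) lie above 0 and B and plasma cell markers (-0.396) below, and most other lists cross or approach 0.

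Of the 7 genes named in advance that could be tested, IL1B, CXCL8, ISG15 and PTGS2 fell, and PGR, OXTR and FOXA2 did not pass. The progesterone receptor PGR was at 0.19 ± 0.093 (SE; edgeR adjusted p = 0.217) and averaged 9.99 ± 4.24 CPM (SD, n = 81) in pregnant and 8.73 ± 3.80 CPM (SD) in nonpregnant cows. The oxytocin receptor OXTR was at 0.15 ± 0.071 (adjusted p = 0.206). PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, fell by 1.11 ± 0.34 on the log2 scale (adjusted p = 0.0291), to 48.4 CPM in pregnant cows. Its medians lay closer, at 29.8 CPM in pregnant and 33 CPM in nonpregnant cows, with the pregnant cow higher in 45.9% of pairs (Wilcoxon adjusted p = 0.717). Without nonpregnant replicate 66 PTGS2 was at -0.95 and no longer called (adjusted p = 0.0695), and among cows above 45000 it was at -1.14 (adjusted p = 0.0738). ESR1, MX1 and IGF1 had too few assignable reads for the filter, S100A8, S100A9, LTF, SPP1 and MUC1 had 0 counts in all libraries, and MKI67 was not matched by name.

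Pregnancy was predicted above chance, with a modest accuracy. An elastic-net logistic regression on the 2000 most variable genes, chosen within each training fold, gave an area under the ROC curve of 0.662 ± 0.0203 (SD over 10 repeats of 5-fold cross-validation, 193 cows). The predictions averaged over repeats gave 0.69, with a bootstrap 95% interval from 0.616 to 0.766. Among 100 permutations of the outcome labels the highest area was 0.598 and the median 0.495, so that the 1-sided permutation p was 0.0099, the smallest that 100 permutations can give. PPP1R3C, a regulatory subunit that targets protein phosphatase to glycogen, entered all 50 models with a negative weight. Its level was lower in pregnant cows (-1.06 ± 0.21, edgeR adjusted p = 0.000228, Wilcoxon adjusted p = 0.0214) but averaged only 0.814 CPM over all cows. GDF7 (0.893 CPM) and AZU1 (0.797 CPM), given next, also averaged under 1 CPM. The locus LOC101907523 (49 models; 0.57 ± 0.16, adjusted p = 0.0131), GARIN4 (46 models; 0.48 ± 0.18, adjusted p = 0.0969), the growth factor GDF7 (45 models; 0.37 ± 0.21, adjusted p = 0.349), AZU1 (26 models; 0.35 ± 0.21, adjusted p = 0.347) and the testis-type linker histone H1-7 (26 models; 0.41 ± 0.25, adjusted p = 0.375) had positive weights. The purinergic receptor P2RY13 (43 models, -1.34 ± 0.23, adjusted p = 8e-06) and CLSTN3 (26 models, -0.74 ± 0.19, adjusted p = 0.00712) had negative weights. Among the 10 most selected, 2 further transcripts had no gene symbol. TPSB2, with negative weights, and other transcripts without a symbol also entered 26 models, so the last of the 10 places rest on a tie. Among cows above 45000 LOC101907523 (0.53, adjusted p = 0.0828) and CLSTN3 (-0.61, adjusted p = 0.0663) did not pass. Among the 161 cows above 45000 the averaged predictions gave an area of 0.656 (1-sided permutation p = 0.0002), and the other blocks held too few pregnant cows for an area of their own. This p came from 20000 permutations and cannot be set beside the 0.0099 of 100 permutations. The cow number alone gave 0.624 ± 0.0081, IL1B alone 0.569 ± 0.006 and the unfolded protein response score alone 0.618 ± 0.0053.

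**Figure D3:**
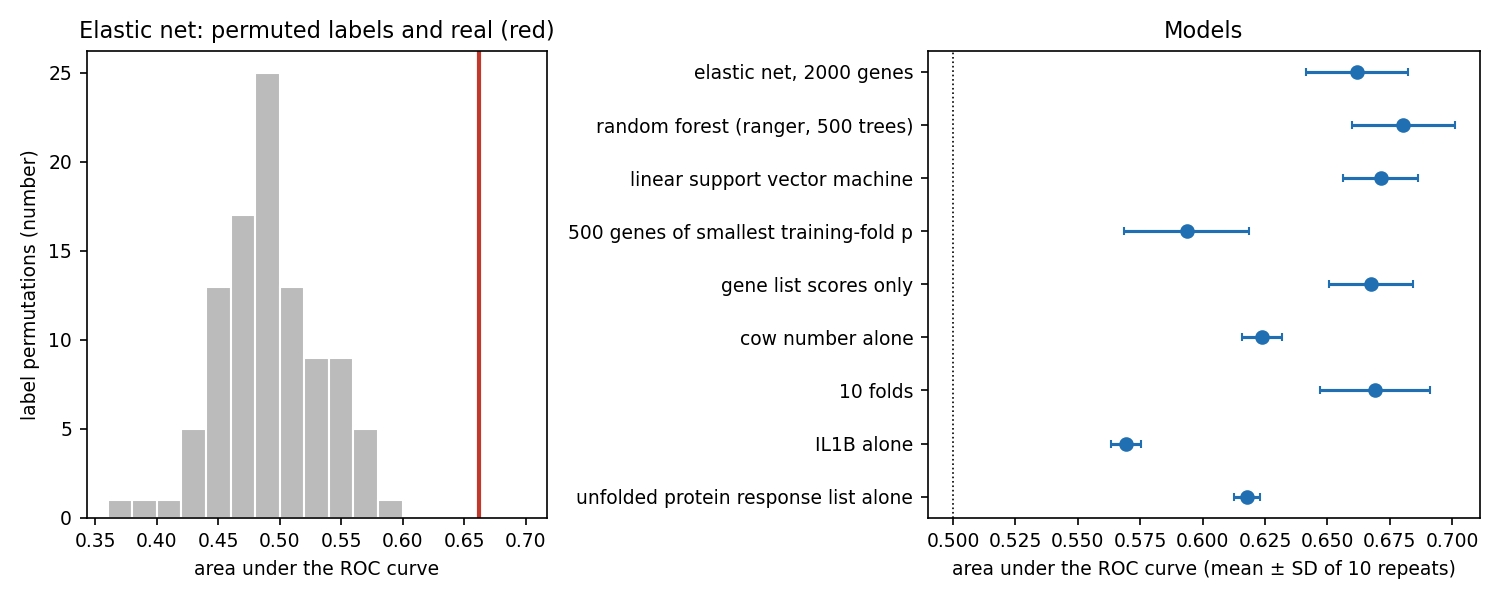
Left, areas under the ROC curve of the elastic net for 100 permutations of the outcome labels (grey) and for the real labels (red line, 0.662); right, mean area ± SD over 10 repeats for each model, with the dotted line at chance. The real value lies above the highest permuted area of 0.598, and the random forest (0.68) and the support vector machine (0.671) lie within the repeat spread of the elastic net.

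Where genes differed in spread between cows, the nonpregnant group was mostly the wider. The sphingolipid enzyme subunit SPTSSB had an SD of log2 CPM of 0.482 in pregnant and 0.934 in nonpregnant cows, and GDF7 an SD of 0.945 and 1.43, the 2 genes called for a difference in spread among 11168 (Brown-Forsythe test with Benjamini-Hochberg adjustment, adjusted p = 0.045 for both). On residuals after 5 cell list scores neither was called (adjusted p = 0.133 for SPTSSB and 0.11 for GDF7). GDF7 averaged only 0.893 CPM over all cows, and spread from counting at so low a level was not separated from spread between cows. At an unadjusted p under 0.05 there were 1646 genes, against 558 expected, and 1625 of them were wider in nonpregnant cows. The 558 is 0.05 of the genes tested. Genes vary together across cows, and this count was not taken with shuffled outcomes, so how far it varies by chance is not known. GARIN4, the acid phosphatase ACP3, TTC39C, ITFG2, TTC4 and the actin-binding CORO1C had the next smallest p among genes with a symbol, with adjusted p from 0.0551 to 0.0923, and each was wider in nonpregnant cows. The mean correlation of a library with all others was 0.93 ± 0.00997 (SD, n = 81) in pregnant and 0.922 ± 0.0151 (SD) in nonpregnant cows (2-sided permutation p = 8e-05). Below a limit of 0.906, set at 3 median absolute deviations under the median, were 2 of 81 pregnant and 17 of the nonpregnant libraries (2-sided Fisher exact test, p = 0.00294). When these libraries were left out 122 genes were called for a difference in mean (32 higher, 90 lower). These values were not computed within cow number blocks.

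Of the first 10 principal components of the 2000 most variable genes, 3 differed between outcomes. Component 2, with 10.3% of the variance, had immunoglobulin, JCHAIN and stromal genes at one end and the uterine serpin SERPINA14 at the other, and was lower in pregnant cows at -4.34 ± 16.3 (SD, n = 81) against 3.14 ± 22.6 (SD) (2-sided permutation test, adjusted p = 0.0423 over 10). Component 4, with 3.19%, placed LAP, KRT4, IL1B and CXCL8 at the end away from pregnant cows (2.46 ± 7.73 against -1.78 ± 13.3, permutation adjusted p = 0.0423). Component 7, with 1.98%, set AHSG and SERPINA14 against OLFM4 and TFF1, and pregnant cows lay toward OLFM4 and TFF1 (-2.92 ± 7.31 against 2.11 ± 9.56, permutation adjusted p = 0.001). The leading component, with 26.7% of the variance, did not differ (permutation p = 0.509). With the 5000 most variable genes components 2 (permutation adjusted p = 0.241) and 4 (adjusted p = 0.0559) did not pass. Components 3, 6 and 7 did (adjusted p = 0.00787 each). The components of both gene sets were not matched, so a number need not stand for the same axis in each. These genes were chosen as the ends of each axis after its loadings were seen, and the components were not computed within cow number blocks.

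Markers of different cell types varied together across cows. Of 55 pairs among 11 cell type lists 40 were related (2-sided permutation of Pearson's r, Benjamini-Hochberg over 55), 24 positively and 16 negatively, and all 40 had the same sign in both outcome groups. The strongest relation was between stromal fibroblast and smooth muscle markers, with r = 0.764 and rho = 0.838 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give; adjusted p = 2.5e-05 and 2.9e-05), r = 0.757 without the 2 farthest cows, and r = 0.718 in pregnant and 0.775 in nonpregnant cows. Macrophage and T and NK cell markers had r = 0.69 and rho = 0.67 (permutation p = 1e-05 for both, adjusted p = 2.5e-05 and 2.9e-05), with r = 0.651 without the 2 farthest cows and 0.612 and 0.721 within pregnant and nonpregnant cows. Glandular and mucus-secreting markers, which share 1 member, had r = 0.642 and rho = 0.576 (permutation p = 1e-05 for both, adjusted p = 2.5e-05 and 2.9e-05), with r = 0.571 without the 2 farthest cows and 0.662 and 0.646 within the groups. General epithelial markers varied against B and plasma cell markers, with r = -0.317 and rho = -0.32 (permutation p = 1e-05 for both, adjusted p = 2.5e-05 and 2.9e-05), r = -0.26 without the 2 farthest cows, and r = -0.491 in pregnant and -0.245 in nonpregnant cows. These relations were not computed within cow number blocks.

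**Figure D4:**
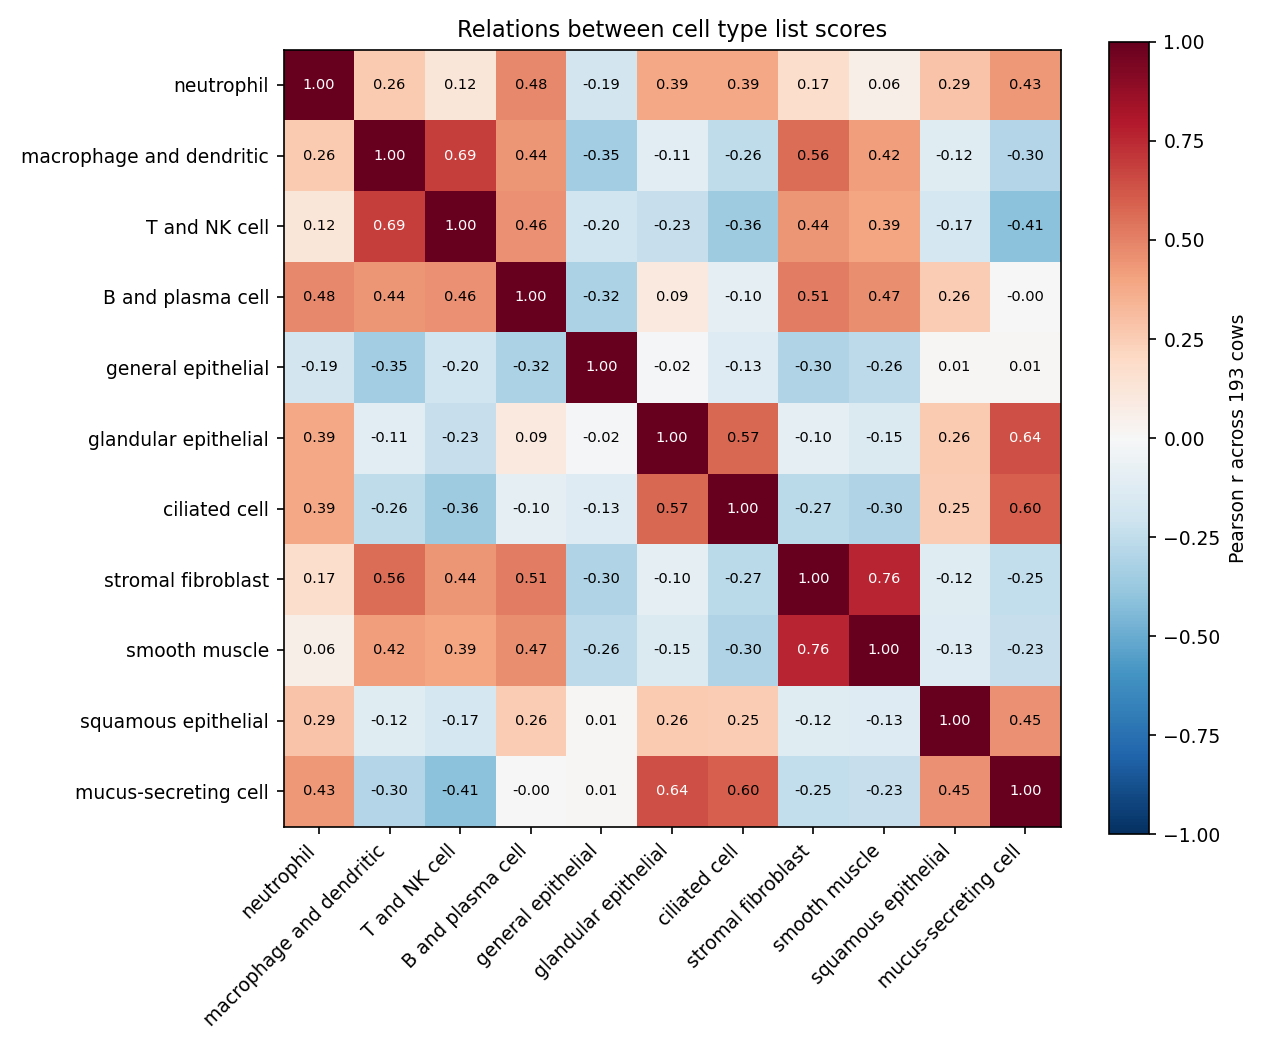
Pearson correlation across 193 cows between the scores of 11 cell type marker lists, on a colour scale from -1 to 1. Stromal fibroblast and smooth muscle markers (0.764), macrophage and T and NK cell markers (0.69) and glandular and mucus-secreting markers (0.642) form the strongest pairs, and general epithelial markers run against immune and stromal markers.

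The number printed in each sample's title, whose meaning the labels do not give, was related to the outcome. Pregnant cows had a mean rank of 112.4 ± 54.1 (SD, n = 81) and nonpregnant cows 85.9 ± 54.7 (SD), a difference of 26.5 ± 7.93 (2-sided permutation test, p = 0.0011). Pregnant were 3 of 16 cows numbered below 20000 (18.8%, Wilson 95% interval 6.59% to 43%), 5 of 16 between 20000 and 45000 (31.2%, 14.2% to 55.6%) and 73 of 161 above 45000 (45.3%, 37.9% to 53.1%). The difference between blocks did not pass (2-sided Fisher exact test, p = 0.0823), and the ranks still differed within the 161 cows above 45000, by 17.4 (2-sided permutation test, p = 0.0181).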

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

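The comparison of library measures, the cap, the ambiguous share covariate, the score difference, the demand that a setting leave most calls of the other direction and the reading of other settings and splits as tests of a cause were chosen only after the results were seen. The share of reads that fitted more than 1 transcript, which entered none of the comparisons fixed in advance, differed between the outcomes and is given here for that reason. It averaged 49.9% ± 1.14 (SD, n = 81) in pregnant and 49.3% ± 1.46 (SD) in nonpregnant cows, a difference of 0.614 ± 0.188 (SE; 2-sided permutation test, p = 0.00185, adjusted p = 0.0148 over 8 library measures). The unfolded protein response score was related to it, with r = 0.252 and rho = 0.222 (permutation p = 0.00042 and 0.002, adjusted p = 0.000504 and 0.003 over 6 relations), r = 0.227 without the 2 farthest cows, r = 0.215 and rho = 0.103 in pregnant cows, and r = 0.209 and rho = 0.238 in nonpregnant cows.

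The first pattern weighed was the lower level of 511 genes in pregnant cows, for which 56 distinct cows had the highest level of at least 1 gene. With the rank of the cow number as a covariate 63.6% of calls were kept, which argues against a linear trend with that number as the whole cause. Among the fewer cows above 45000, 183 of the 511 were kept, and 499 had the same sign, with a median of -0.49 ± 0.17. A linear term cannot exclude groups of cows that the number may stand for, so these stay open. Chance was excluded for the total of 657 called genes only at the share of 1 of 100 splits of the same cows, the real one. The splits were not made within cow number blocks. The highest other split called 191 genes, and the median of the other splits was 15. A single edgeR call can therefore come from chance more often than its adjusted p states. Capping each gene at its 95th percentile left 20.4% of the 511 calls, with a median log2 fold change of -0.38 ± 0.14 (median SE) against -0.64 ± 0.17 uncapped, but the cap removes the very values in question and left only 51 of the 146 higher calls (0.21 ± 0.064 against 0.23 ± 0.067), so it stays open how far a minority of nonpregnant cows with very high levels made these calls. With 5 cell list scores as covariates 16.2% of the 511 were kept and the median was -0.23 ± 0.13, but the scores hold some of the called genes and 6.85% of the higher calls were kept, so more immune and stromal cells in some nonpregnant samples stay open too. No biological explanation was tested.

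The second pattern was the higher level of 146 genes in pregnant cows, protein folding genes among them. A larger epithelial share stays open. The unfolded protein response score exceeded the general epithelial score more in pregnant cows, by 0.313 ± 0.117 (2-sided permutation test, p = 0.00807). But the former score also spread more between cows, with an SD of 0.809 against 0.448 in pregnant cows. A shared cause could therefore move it more, and the difference of the scores cannot decide. With 5 cell list scores as covariates 6.85% of the 146 calls were kept, with a median of 0.18 ± 0.062. With the rank of the cow number as a covariate 65.8% of the 146 calls were kept, which argues against a linear trend with that number as the whole cause. Among the fewer cows above 45000, 36 of the 146 were kept, all 146 with the same sign and a median of 0.22 ± 0.071. Groups of cows that the number may stand for stay open, since a linear term cannot exclude them. With the share of ambiguous reads as a covariate 3 of the 146 calls (2.06%) were kept, all 146 with the same sign and a median of 0.17 ± 0.064 against 0.23 ± 0.067, and counting and biology cannot be told apart here, since the ambiguous share may itself follow the expression of genes with several transcripts. For the 12 called lists 3 of 100 splits reached that number, the real one included, so chance was excluded only at that share, and with 15 as the highest other and a median of 4 lists in the other splits, a single camera call is weak evidence.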

How the results depend on the processing

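Settings called added below were chosen after the data were seen. The 657 genes called for a difference in mean stayed within 1.5 times under DESeq2 size factors (665), the DESeq2 Wald test (775), robust edgeR (654), a mean of at least 5 CPM (489), composition covariates (834) and the cow number as block (494) or rank (449), and in the added settings of counts per transcript (639), genes with 1 transcript (555) and a squamous score covariate (488). Without each of 23 cows in turn (added) the count ran from 502, without nonpregnant replicate 15, to 721, without nonpregnant replicate 27. As a percent of the 11168 genes the calls were 5.88%, and 0.0537% (6 genes) with limma-voom, 0.994% with the Wilcoxon test, 1.09% without 19 libraries of low correlation, 1.03% with 5 cell scores, 1.23% with 5 surrogate variables and 0.627% with 3 principal components as covariates. In added settings they were 1.41% with the cap at the 95th percentile, 1.98% among cows above 45000, where fewer cows were tested, and 0.779% with the ambiguous share as a covariate. With no filter 2229 of 33048 genes were called, or 19.96% of the same 11168, more genes being tested. Apart from fewer cows and more genes, the cause was not tested. Of 62 called named genes 62 stayed past the threshold with DESeq2 size factors, 54 with the cow number rank, 32 with the cap, 19 by the Wilcoxon test and 1 with limma-voom.

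Over all named genes and settings 1357 of 1785 fold changes kept direction and side of the threshold, 386 lost the call, 12 gained one and 30 changed sign. With limma-voom IGFBP1 was at 0.17, MMP9 at 0.031 and KRT5 at 0.22. By the Wilcoxon test pregnant cows were higher in 51.8% of pairs for IGFBP1, 50.4% for MMP9, 58.5% for KRT5 and 55.5% for MUC5AC. KRT5 was also positive with the DESeq2 Wald test (0.11), without libraries of low correlation (0.39) and with the cap (0.24), as was MUC5AC with the cap (0.034). With 5 cell scores MMP9 was at 0.46, COL3A1 at 0.010, COL1A2 at 0.026, THY1 at 0.12, SYNPO2 at 0.052 and CXCL12 at 0.14. The 5 scores were those of neutrophil, general epithelial, stromal fibroblast, T and NK cell and erythroid markers. MMP9 is part of the neutrophil score, and COL3A1, COL1A2 and THY1 are part of the stromal score. Adjusting for these scores therefore removes part of the difference of these genes by design. With 5 surrogate variables COL3A1 was at 0.017, COL1A2 at 0.0085, THY1 at 0.082, DES at 0.14, SYNPO2 at 0.18, ACTG2 at 0.45, KRT5 at 0.45 and CXCL12 at 0.15. With 3 principal components THY1 was at 0.099, DES at 0.098, SYNPO2 at 0.072, ACTG2 at 0.31 and CXCL12 at 0.21. None of these positive values was called, and apart from that overlap the cause was not tested.

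The 12 lists called by camera became 13 with the cow number block, 14 with DESeq2 size factors and, in an added setting, 15 of 36 with members of at least 0.1 CPM. With 5 cell scores 4 of 27 lists were called, with fry 3 (12 at an unadjusted p under 0.05), and by camera with an estimated correlation 0 (3 at an unadjusted p under 0.05). The 3 called list scores became 5 with the median over members, 6 unstandardized and, in added settings, 7 with DESeq2 size factors and 5 with members of at least 0.1 CPM. The area under the curve of 0.662 was 0.594 with the 500 genes of smallest training-fold p and 0.624 with the cow number alone, and in added settings 0.569 with IL1B alone and 0.618 with the unfolded protein response alone, where fewer variables were used. It was 0.68 with a random forest, 0.671 with a support vector machine, 0.668 with list scores and 0.669 with 10 folds. The 2 genes called for spread became 24 with the Levene test from the mean (1841 at an unadjusted p under 0.05) and 0 by the Brown-Forsythe test on residuals after 5 cell scores (1381 at an unadjusted p under 0.05). The cause was not tested. Of 10 principal components, 2, 4 and 7 differed with 2000 genes and 3, 6 and 7 with 5000, the axes of both sets not being matched. No library had under 0.5 times the median total, so leaving such libraries out removed nothing and gave no value for any result. Assignable reads limited which genes could be tested. Of the 11168 tested, 8631 had 1 transcript under their name, transcript names without a matched symbol included.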

Other observations

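The tests of prediction and spread against other causes in this part were chosen only after the results were seen. Lists that did not pass camera still held called genes. Of 14 progesterone-phase and receptivity genes 6 fell, and 8 when adjusted over the list alone (limma camera, adjusted p = 0.219), of 5 antimicrobial peptides 3 fell, and 3 when adjusted over the list alone (adjusted p = 0.718), and of 10 Wnt signalling genes 3 fell, and 4 when adjusted over the list alone (adjusted p = 0.295). Of 13 matrix proteases and inhibitors 3 fell, and 4 when adjusted over the list alone (adjusted p = 0.838). The Wilcoxon test called 0 genes in each of these lists. At an unadjusted p under 0.05 it had 1 progesterone-phase, 1 antimicrobial, 2 Wnt and 1 matrix gene. None of 30 ribosomal protein genes and 13 mitochondrially encoded genes passed edgeR, with 0 at an unadjusted p under 0.05 in either list and 0 called by the Wilcoxon test.

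Hemoglobin beta (HBB), abundant in red blood cells and too low for the filter, was chosen after its values were seen and was at -0.19 ± 0.37 (edgeR without a filter, adjusted p = 0.837). The cow number was related to 730 genes with the outcome in the model (edgeR, Benjamini-Hochberg), 501 rising and 229 falling with it, and to 603 among cows above 45000, and 506 were called in both with the same sign. The genes of smallest p were mostly named by a locus number only, led by LOC617654, which rose by 1.38 ± 0.11 per 100 ranks. The heat shock gene DNAJB1, chosen after its values were seen, rose by 0.54 ± 0.061 per 100 ranks and by 0.68 ± 0.079 among cows above 45000.

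The third pattern weighed was prediction above chance. The cow number may contribute, since it predicted outcome by itself and the prediction score was related to it (rho = 0.239), but between cows of the same of 8 strata of that number the area was 0.669 over 1055 pairs (1-sided permutation test, p = 0.00015), which argues against it as the whole cause. That p came from 20000 permutations, against 100 for the area over all cows. Chance was excluded for the area of 0.662 only at the smallest p that 100 permutations can give, 0.0099 (1-sided permutation test). None of the 100 permutations reached that area, with 0.598 as the highest. For the 2 genes called for spread chance was excluded only at the share of 1 of 100 splits, the real one. The highest other split called 1 gene. No biological explanation was tested for the prediction, and it was not tested on other cows.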
